A study of Macaca fascicularis with 24 samples.

How the data were processed

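RNA from the thoracic aorta of cynomolgus macaques (Macaca fascicularis) was measured on 24 single-colour microarrays, 6 for each combination of age (old or young) and sex. Per the labels' protocols, total RNA was extracted from each aorta sample with phenol and chloroform, reverse-transcribed and labelled with biotin through a commercial RNA labelling kit. The groups and the replicate numbers were taken from the sample titles. The labels give 1 mean age per group, 21.2 years for old females, 20.0 for old males, 7.2 for young females and 6.6 for young males, and no age for a single animal.

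The deposited values are linear intensities, 1 per probe set (the group of short probes on the array that reads 1 transcript), for 22277 probe sets of a human expression array. The way in which the authors summarised probes into probe sets and scaled the arrays is not given in the sources used here. In the deposited intensities the mean of the middle part of the probe sets, with the brightest and the dimmest left out, lay between 499.8 and 499.9 on every array, so each array had been brought to 1 common level. The array medians still ran from 144.2 to 264.1, or from 7.32 to 8.13 after log2(intensity + 16). Human probes were read with monkey RNA, so a mismatch between the species can lower the signal of a probe set on all arrays alike and can leave it below the filter. The number of arrays limits the precision.

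The 62 control probe sets were left out of the tests. Intensities were converted to log2(intensity + 16), and because the array medians spanned 0.81 on that scale, above the limit of 0.5 set beforehand, the arrays were quantile normalised. The pseudocount of 16 understates the change of dim genes. Of the 22215 other probe sets, those whose mean over all arrays lay at or above the median of these means were tested, 11108 in all. Gene symbols came from the platform annotation: 19064 probe sets had 1 symbol, 1043 had several and were given no name, and 2108 were not named here.

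Before testing, all 276 pairs of arrays were compared. In 3 pairs (old females 1 and 4, young males 3 and 4, young females 3 and 4) the arrays were far closer to each other than any other pair. The SD of their log2 difference was at most 0.38, against at least 0.43 in the other pairs. The correlation of their deviations from the mean of the other arrays outside these pairs was at least 0.81, against at most 0.50. Each such pair was averaged and counted as 1 sample, named by its lower number, which left 21 samples: 5 old females, 6 old males, 5 young females and 5 young males. This departs from the design fixed beforehand, which counted 24 arrays, and the count of 24 was kept as an alternative. The labels do not say whether the arrays of such a pair come from 1 animal.

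A linear model with a mean per group was fitted to the 21 samples with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The 6 contrasts were old against young in males, in females and averaged over both sexes, the difference of the 2 age effects (the interaction), and male against female in young and in old animals. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Errors given with the log2 change of a gene are standard errors from this model, and n is the number of samples. Errors given with a list median are standard errors of the list mean over samples, from an ordinary linear fit. Replicate numbers were not used to pair animals.

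Gene lists for aortic cell types, matrix, metabolism, signalling and other cell functions, 42 in all, were fixed before the data were examined. Each gene was represented by its brightest probe set on average, which gave 6943 genes. Camera, limma's competitive test of a list against all other genes, was run with a preset correlation of 0.01 on the 40 lists with at least 5 tested members, and its p-values were adjusted over the lists of a contrast. It was repeated with a correlation estimated from the data, and fry, limma's self-contained rotation test, was run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Camera had first been run with a trended variance, which called 1 more list in each of 3 contrasts, and was then set to its default, as the design was written. The age effects of the sexes were correlated across genes and compared with 100 permutations of the age labels within each sex, the real labels included.

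The genes named in the text followed a rule set beforehand. For each contrast, up to 12 higher and 12 lower genes past the threshold with the largest log2 change were taken, with 1 probe set per gene. Where fewer than 10 passed, the genes with the smallest p filled up to 10 and are named as not passing. Up to 4 members with the smallest p were named for each list described, and XIST and the Y-linked genes were always named for the sex contrasts.

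The model was tested on simulated data for the male age contrast with 11108 probe sets. It recovered 45 of 100 simulated log2 changes of 1 and 96 of 100 changes of 2, with 8 false among 149 calls. The noise was drawn separately for each probe set, with no structure shared between them, so recovery in the real data can be lower. A collagen list shifted by -0.5 was called and 0 other lists were, on simulated genes that were independent of each other, which real genes are not.

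Alternatives set beforehand covered the scaling between arrays, the filter on dim probe sets, pseudocounts of 1 and 64, the replicate number as a block, no intensity trend, array weights, 1 probe set per gene, the fit of only the 2 groups compared and leaving out each sample in turn. For the gene lists, only the estimated correlation, fry, no filter, the deposited scale and the replicate block had been set beforehand. Chosen after seeing the data were the other settings for the lists, the count of 24 separate arrays, the fit without 6 divergent samples, 2 measures of array quality as covariates, the trended variance in camera, and the X-linked list without XIST. The series' design text speaks of about 600 genes that differed between old and young animals, with no test or threshold given in the sources used here.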

Results

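Gene expression was measured in the thoracic aorta of old and young cynomolgus macaques of both sexes, to ask how the aorta's transcripts differ with age and whether they do so differently in males and females. After 3 pairs of near-identical arrays had each been averaged, 21 samples were compared: 5 old females, 6 old males, 5 young females and 5 young males. The probe sets were designed for human transcripts and read here with monkey RNA.

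Nothing in the labels says that replicates are separate animals, beyond 1 mean age per group, so the p-values measure the spread between samples. Arrays also differed from each other within groups. On 7 of the 24 arrays, the median correlation with all other arrays lay between 0.81 and 0.83, against 0.88 to 0.93 on the rest. The spiked-in hybridisation controls read 12.52 to 13.97 (mean log2 intensity) on these arrays and 10.9 to 11.9 on the others. The log2 ratio of the 3′ to the 5′ actin control, a measure of RNA degradation, was 0.78 to 1.73 against -0.25 to 1.15. The 7 arrays make up 6 samples: old females 2 and 6, old males 2 and 4, young female 3 and young male 1. The limit of 0.85 that separates them was chosen after their values were seen. The first principal component of all samples held 30.6% of the variance and the second 10.4%. On the first, the 6 divergent samples scored 0.27 to 0.37 and all other samples -0.22 to -0.008, so it set the divergent samples apart.

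**Figure D1:**
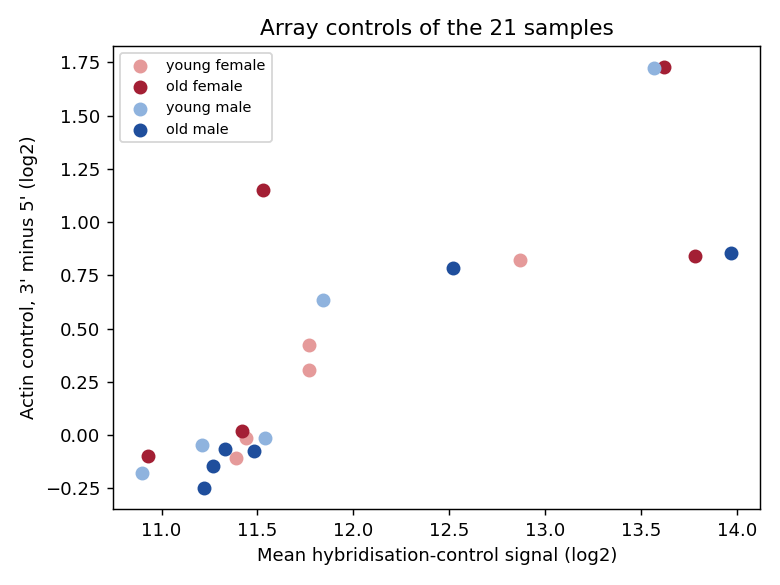
Mean hybridisation-control signal (log2, horizontal) against the 3′ minus 5′ actin control (log2, vertical), 1 point per sample, coloured by group, for 21 samples. Samples with a control signal above 12 are the 6 divergent ones.

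In males, ACAN was higher in old than in young animals. ACAN encodes aggrecan, a large proteoglycan known from cartilage and also present in the vessel wall. The first of its probe sets rose by a log2 change of 3.10 ± 0.51 (SE, limma adjusted p = 0.0478), from 7.29 ± 0.38 (SD, n = 5) in young to 10.39 ± 1.31 (n = 6) in old males. Each of the 6 old males, at 8.67 to 12.17, lay above each of the 5 young males, at 6.72 to 7.79. A second ACAN probe set rose by 2.70, and on the third, which did not pass, the means were 9.47 ± 1.37 in old and 7.24 ± 0.61 in young males.

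These 2 probe sets were the only ones of 11108 past the threshold in males, while 373 had an unadjusted p below 0.05 in limma (171 higher, 202 lower) and 555 are expected by chance. Genes with the next smallest p did not pass. Lower means in old males were measured for PI15 (log2 change -1.44 ± 0.31), MINAR1 (-1.94 ± 0.43), NREP (-1.02 ± 0.24), COL1A2 (-0.96 ± 0.23), ENPP1 (-0.86 ± 0.23) and ADGRL1 (-0.93 ± 0.27). Higher means were measured for ID1 (0.91 ± 0.24), HADH (0.99 ± 0.28) and AKR1B10 (1.55 ± 0.44), with limma adjusted p-values from 0.553 to 1 over these 9 genes. PI15 encodes a secreted peptidase inhibitor, COL1A2 a chain of type I collagen, ENPP1 an enzyme that makes pyrophosphate, and ID1 an inhibitor of transcription factors downstream of BMP. HADH acts in fatty acid oxidation, and AKR1B10 reduces aldehydes. Leaving out 1 male sample at a time left 0 to 2 calls, and 0 remained with each array centred on its median or with no filter. Array weights gave 20 calls, among them both these ACAN probe sets and the third ACAN probe set (2.90, limma adjusted p = 0.0298).

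Several gene lists lay away from the other genes in males, although random splits of the male samples also called a median of 7 lists. Of 14 adipocyte markers, 13 had a higher mean in old males, with a median log2 change of 1.34 (camera adjusted p = 1.13e-06; adjusted p = 0.492 with an estimated correlation). Members with the smallest p were CIDEC (1.16 ± 0.40), PPARG (2.12 ± 0.93), FASN (1.72 ± 0.80) and LPL (1.91 ± 0.93), and 0 of the 14 passed limma's threshold, with 3 at an unadjusted p below 0.05. The oxidative phosphorylation list, the nuclear-encoded subunits of the respiratory chain, had a median of 0.28 with 39 of 44 members higher (camera adjusted p = 1.22e-05; adjusted p = 0.551 with an estimated correlation). Without old male 4, a divergent sample, its median was 0.02 (camera adjusted p = 0.494). Its leading members were ATP5MC3 (0.26 ± 0.13), COX8A (0.53 ± 0.30), NDUFV2 (0.39 ± 0.23) and ATP5MC1 (0.50 ± 0.30). The enzymes of cholesterol synthesis and uptake had a median of 0.35 with 16 of 17 members higher, led by MSMO1 (1.05 ± 0.35), EBP (0.72 ± 0.24), FDPS (0.49 ± 0.18) and NSDHL (0.89 ± 0.44). Fatty acid oxidation had a median of 0.36 with 18 of 21 members higher (camera adjusted p = 0.000663; adjusted p = 0.551 with an estimated correlation), but 0.07 and not called without old male 4, and HADH passed when adjusted over the list alone. With the adipocyte list mean of each sample as a covariate, the medians were -0.06 for oxidative phosphorylation (camera adjusted p = 0.512), -0.15 for fatty acid oxidation (0.432), 0.25 for cholesterol synthesis (0.113) and 0.07 for glycolysis (0.406).

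The collagen and elastic fibre lists lay lower in old males. The fibrillar and network collagens had a median of -0.45 with 12 of 15 members lower (camera adjusted p = 0.000221; adjusted p = 0.492 with an estimated correlation), with COL1A2, COL1A1 (-1.12 ± 0.39), COL3A1 (-0.81 ± 0.32) and COL15A1 (-0.59 ± 0.33) in front. Adjusted over the list alone, 1 collagen, COL1A2, passed. All 18 members of the elastic fibre list had a lower mean, with a median of -0.34 (camera adjusted p = 0.000577; adjusted p = 0.492 with an estimated correlation), but -0.05 and not called without old male 4. Among them were FBN1 (-0.79 ± 0.39), LOX (-1.30 ± 0.66), EMILIN1 (-0.80 ± 0.47) and LTBP3 (-0.65 ± 0.38). The proliferation list lay lower with a median of -0.27, and higher medians were measured for glucocorticoid targets (0.35), endothelial markers (0.28, but -0.05 without the 6 divergent samples), glycolysis (0.14) and cell cycle arrest and senescence genes (0.08). Over the alternatives, glucocorticoid targets came down to 0.14, glycolysis to 0.06 and the senescence genes to 0.03. In all, 11 of 40 lists passed in males, 8 higher and 3 lower. None of them held with an estimated correlation, where the adjusted p was 0.492 for 9 lists and 0.551 for oxidative phosphorylation and fatty acid oxidation.

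**Figure D2:**
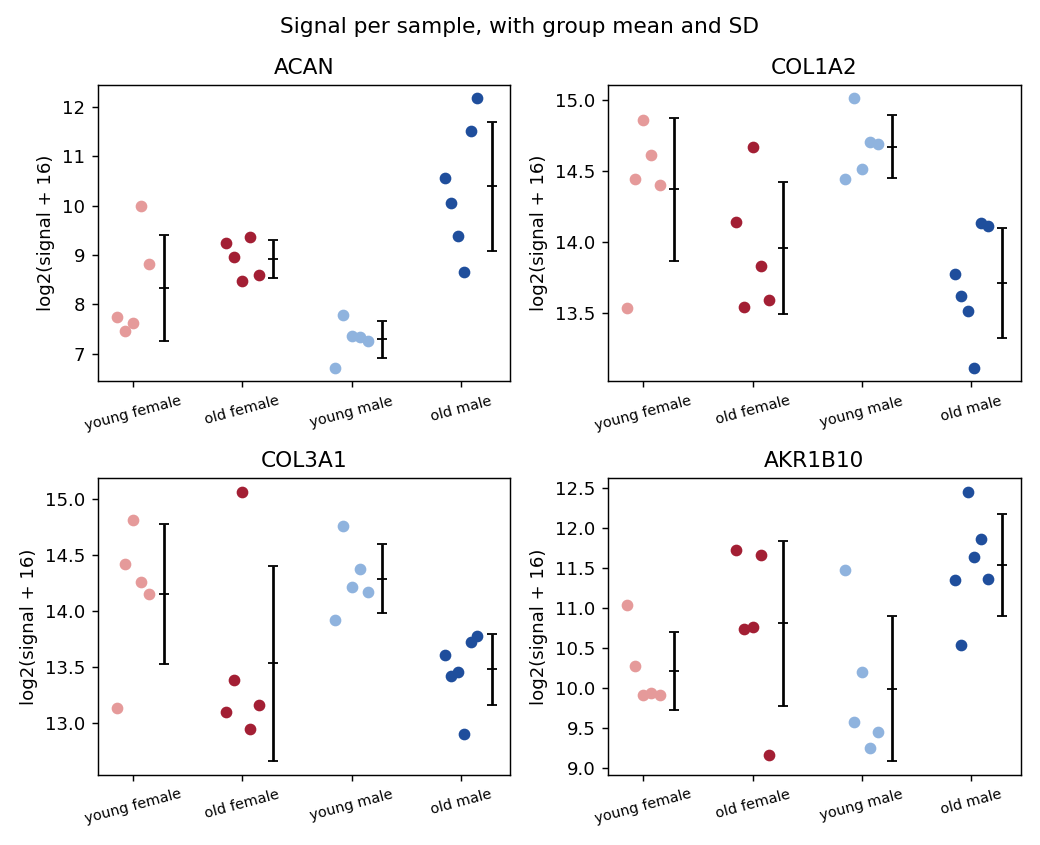
ACAN, COL1A2, COL3A1 and AKR1B10 in the 4 groups, log2(signal + 16) after quantile normalisation, 1 point per sample, with group mean and SD (n = 5 or 6). For ACAN, each old male lies above each young male, while the female groups overlap.

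The same question was asked in females, where no probe set passed. Limma gave 0 calls among 11108 probe sets, with a smallest adjusted p of 0.999, and 316 probe sets (115 higher, 201 lower) at an unadjusted p below 0.05. The genes with the smallest p were HPS4 (log2 change 0.76 ± 0.20), EEIG1 (0.68 ± 0.20) and IRF4 (0.72 ± 0.24) with a higher mean in old females, and PLPP1 (-0.60 ± 0.18), C2CD2 (-0.96 ± 0.30), ITM2C (-0.66 ± 0.21), RHOC (-0.62 ± 0.20), PDE4D (-1.22 ± 0.40), PSMD3 (-0.58 ± 0.19) and RABL6 (-1.15 ± 0.38) with a lower one. HPS4 acts in the making of lysosome-related organelles, PLPP1 degrades lipid phosphates, PDE4D breaks down cyclic AMP, RHOC is a small GTPase and IRF4 a transcription factor of lymphocytes. The first ACAN probe set of the male comparison was at 8.93 ± 0.39 in old and 8.33 ± 1.07 in young females (SD, n = 5 each).

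The smooth muscle, collagen and elastic fibre lists lay lower in old females. Of 21 genes of the smooth muscle contractile apparatus, 20 had a lower mean, with a median of -0.31 (camera adjusted p = 0.00247; adjusted p = 0.934 with an estimated correlation), among them ACTG2 (-0.76 ± 0.38), MYH11 (-0.51 ± 0.32), MYL9 (-0.64 ± 0.41) and MYL6 (-0.24 ± 0.16). The collagens had a median of -0.41 with 13 of 15 members lower, led by COL4A2 (-0.92 ± 0.33) and COL4A1 (-0.54 ± 0.25) of the basement membrane, and the elastic fibre list a median of -0.36 with 16 of 18 lower, but 0.01 with the actin control ratio as a covariate. Macrophage and myeloid markers had a median of 0.38 with 14 of 17 higher, led by CD74 (0.90 ± 0.50), PTPRC (0.97 ± 0.63) and ITGAM (0.55 ± 0.38), and MHC class II genes, which present antigen, a median of 0.48 with 8 of 9 higher, among them HLA-DRA (0.97 ± 0.56). Ribosomal proteins lay higher (median 0.07, but -0.02 with median-centred arrays) and the proteasome list lower (-0.14, but 0.002 without the 6 divergent samples). Over the alternatives, smooth muscle genes came as close to 0 as -0.07, MHC class II genes as 0.09, macrophage and myeloid markers as 0.15 and collagens as -0.19. No member of these 7 lists passed adjusted over the list alone, and with an estimated correlation the adjusted p was 0.934 for each. Without old female 6, a divergent sample, 0 lists were called in females, and without young female 1 there were 4. HBB, the beta chain of haemoglobin, read 10.5 to 15.4 (mean log2 intensity of its probe sets) in old and 8.98 to 15.1 in young females.

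Averaging the age effects of the sexes asked what differs with age in both. Limma gave 0 calls, with 485 probe sets (179 higher, 306 lower) at an unadjusted p below 0.05 and a smallest adjusted p of 0.632. Lower means with age were measured for PI15 (log2 change -1.03 ± 0.23), ENPP1 (-0.69 ± 0.17), COL1A2 (-0.69 ± 0.17), NREP (-0.70 ± 0.17), EXT1 (-0.73 ± 0.18), LRRC17 (-0.95 ± 0.24), PTPRD (-0.91 ± 0.24) and ADGRL1 (-0.74 ± 0.19), and higher means for ACAN (1.85 ± 0.37) and EEIG1 (0.50 ± 0.14), none of them past the threshold. EXT1 is needed for heparan sulfate synthesis, and PTPRD is a receptor phosphatase. The collagen list was lower with age, with a median of -0.42 and 13 of 15 members lower (camera adjusted p = 1.45e-05; adjusted p = 0.767 with an estimated correlation). Adjusted over the list alone, 4 collagens passed: COL1A2, COL1A1 (-0.79 ± 0.29), COL3A1 (-0.71 ± 0.23) and COL4A2 (-0.72 ± 0.23). The elastic fibre list had a median of -0.37 (as little as -0.13 over the alternatives) with 17 of 18 members lower, led by FBN1 (-0.77 ± 0.28) and LOX (-1.16 ± 0.48), an enzyme that cross-links collagen and elastin. The smooth muscle list lay lower (-0.24), although DES had a higher mean (0.84 ± 0.45). Higher medians were measured for adipocyte markers (0.69, 13 of 14), MHC class II (0.33, 9 of 9), macrophage markers (0.23), cholesterol synthesis (0.22), immediate early genes (0.21, down to 0.05 over the alternatives, led by JUNB at 0.77 ± 0.27) and oxidative phosphorylation (0.14, but 0.01 and not called without old male 4). These 9 calls were all lost with an estimated correlation, at an adjusted p of 0.767 for each.

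**Figure D3:**
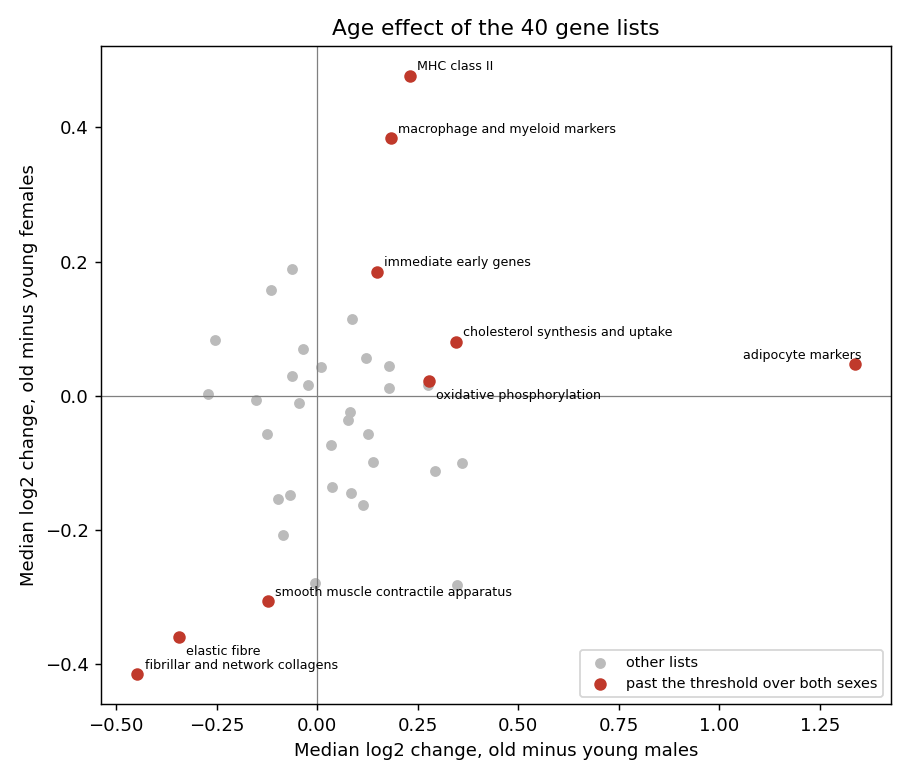
Median log2 change of each of the 40 gene lists, old minus young, in males (horizontal) and in females (vertical), with the 9 lists past the threshold over both sexes in red. Collagens lie at -0.45 in males and -0.41 in females, while adipocyte markers lie at 1.34 in males and 0.05 in females.

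Across 6943 genes, the age effect in males correlated with that in females at r = 0.23 (Spearman's rho 0.20). Genes are not independent replicates, and 25 of 100 permutations of the age labels within each sex, the real one included, gave a correlation as large (2-sided permutation p = 0.25). The difference of the 2 age effects was tested as an interaction. Limma called 0 probe sets, with 215 at an unadjusted p below 0.05 (127 higher, 88 lower). The smallest p-values belonged to PDPK1 (log2 difference -1.17 ± 0.31), IRF4 (-1.22 ± 0.33), GON4L (-1.06 ± 0.29), ARHGAP1 (0.75 ± 0.21), ACAN (2.51 ± 0.74), ENG (1.15 ± 0.34), MINAR1 (-2.07 ± 0.63), HADH (1.24 ± 0.40), CRIP2 (1.16 ± 0.37) and FHL2 (1.35 ± 0.45), none of them past the threshold (smallest adjusted p = 0.9998). PDPK1 is a kinase of insulin signalling, and ENG a TGF beta co-receptor of endothelium. The other tested probe set of PDPK1 had the opposite sign, at an unadjusted limma p not below 0.05. The rise of ACAN in males was therefore not shown to differ from the female value.

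As lists, 12 passed in the interaction, and 0 with an estimated correlation, where the adjusted p of these lists ran from 0.632 to 0.730. The age effect lay higher in males than in females for adipocyte markers (median difference 1.12, 12 of 14 members; PPARG 2.60 ± 1.35), glucocorticoid targets (0.60; ZBTB16 0.88 ± 0.46), cholesterol synthesis (0.42; MSMO1 1.36 ± 0.51), insulin and IGF genes (0.41; IGFBP6 0.50 ± 0.23), fatty acid oxidation (0.36, but 0.03 and not called without old male 4) and glycolysis (0.29; ALDOA 0.72 ± 0.29). It also lay higher for smooth muscle genes (0.29, but -0.03 without old female 6), the proteasome (0.27, but 0.006 without the 6 divergent samples), oxidative phosphorylation (0.25, 39 of 44, but 0.02 and not called without old male 4) and heat shock genes (0.22). Over the alternatives, insulin and IGF genes came down to 0.06 and heat shock genes to 0.07. The age effect lay lower for proliferation genes (-0.29) and ribosomal proteins (-0.11, 34 of 42). Without the 6 divergent samples, 3 lists were called. Leaving out young female 2 left 5 lists, and leaving out young female 6 left 7.

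The comparison of males with females at each age asked which transcripts differ by sex. Genes of the sex chromosomes separated the sexes at both ages. RPS4Y1, a ribosomal protein gene of the Y chromosome, was higher in males by a log2 change of 5.10 ± 0.34 in young (limma adjusted p = 1.01e-08) and 5.58 ± 0.33 in old animals (7.41e-10). XIST, the non-coding RNA that silences 1 X chromosome in females, was lower in males, with a log2 change of -4.36 ± 0.52 in young (0.000121) and -4.56 ± 0.50 in old animals (2.65e-05) on the brighter of its probe sets and of -3.19 at both ages on the other. These 3 probe sets were the only ones past the threshold at either age. Young male 1 read 10.3 for XIST on the brighter probe set, against 6.09 to 7.15 in the other young males and 11.5 to 12.4 in young females. Most Y-linked genes were too dim for the filter, and with all 22215 probe sets DDX3Y (3.41 in young, 2.72 in old) and EIF1AY (3.15 and 2.82) also passed at both ages, and KDM5D in old animals (2.05). USP9Y, ZFY and the other Y-linked probe sets did not pass, UTY among them with 1.51 ± 0.40 in young animals in the filtered fit.

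**Figure D4:**
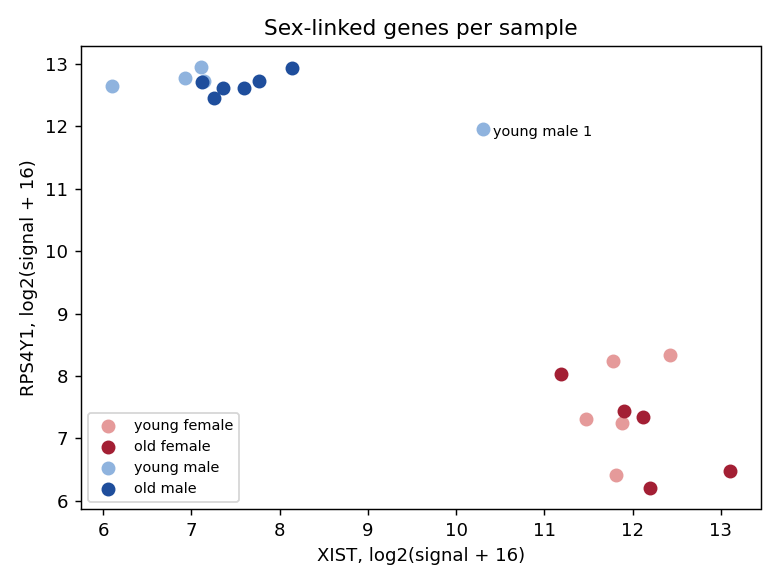
XIST (brighter probe set, horizontal) against RPS4Y1 (vertical), log2(signal + 16), 1 point per sample, coloured by group. All males lie at 11.96 to 12.95 for RPS4Y1 and all females at 6.20 to 8.34, and young male 1 has an XIST signal of 10.3.

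In young animals, 156 probe sets had an unadjusted p below 0.05 (71 higher, 85 lower in males). Genes that did not pass included ATF3 (log2 change 1.82 ± 0.49), MINAR1 (1.80 ± 0.45) and ZNF574 (1.35 ± 0.41) with a higher mean in males, and HLA-B (-0.72 ± 0.21), ENG (-0.83 ± 0.25), FCGR1BP (-1.64 ± 0.52) and KCNH2 (-1.26 ± 0.40) with a lower one. The other tested probe set of KCNH2 had the opposite sign. The X-linked list held XIST, read from the inactive X chromosome alone, and genes known to escape inactivation, which females express from both X chromosomes. This list was lower in males with a median of -0.26 and 10 of 13 members lower (camera adjusted p = 2.05e-06). The call held with an estimated correlation (adjusted p = 0.0127) and in fry (0.0191). Without XIST, the other 12 genes had a median of -0.25 (camera adjusted p = 0.00191; adjusted p = 0.203 with an estimated correlation, 0.575 in fry). Adjusted over the list alone, XIST and DDX3X (-0.47 ± 0.16) passed. All 17 macrophage and myeloid markers had a lower mean in young males (median -0.38, camera adjusted p = 1.05e-05), led by MRC1 (-1.09 ± 0.46) and CD163 (-0.83 ± 0.38), at an adjusted p = 0.356 with an estimated correlation. Lower medians were also measured for adipocyte markers (-0.66), glucocorticoid targets (-0.41), fibroblast markers (-0.34), fatty acid oxidation (-0.27), matrix proteases (-0.26, but 0.03 without the 6 divergent samples), glycolysis (-0.23) and the interferon and MHC class I list (-0.09), where HLA-B passed adjusted over the list alone. Higher medians were measured for skeletal and cardiac muscle markers (0.26), ion channels (0.20) and smooth muscle genes (0.14, but -0.02 without young female 3, a divergent sample), and these 10 lists had adjusted p-values of 0.299 to 0.707 with an estimated correlation. Over the alternatives, fatty acid oxidation came as close to 0 as -0.06 and ion channels as 0.03. Skeletal and cardiac muscle markers came down to 0.11 and kept their call in 8 of 27 alternatives. In place of 12 lists, 6 were called without young female 3, 6 without young male 5 and 5 without young male 6.

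In old animals, 453 probe sets had an unadjusted p below 0.05 (229 higher, 224 lower in males). Lower means in males, not past the threshold, were measured for TCIRG1 (log2 change -0.82 ± 0.19), PDPK1 (-0.83 ± 0.21), DDX3X (-0.58 ± 0.15) and IRF4 (-0.84 ± 0.23), and higher means for PRDM4 (0.78 ± 0.19), TMEM204 (0.96 ± 0.25), TEX2 (0.74 ± 0.20) and SPRY4 (0.87 ± 0.24). The other tested probe set of PDPK1 had the opposite sign here too. The X-linked list was lower in males with a median of -0.26 and 12 of 13 members lower, and it held with an estimated correlation (adjusted p = 0.0147) and in fry (0.00534). Without XIST its median was -0.26 with 11 of 12 lower (camera adjusted p = 0.000688; adjusted p = 0.142 with an estimated correlation, 0.175 in fry). Macrophage and myeloid markers had a median of -0.69 with 15 of 17 lower in males (camera adjusted p = 7.71e-08; adjusted p = 0.466 with an estimated correlation), and TYROBP (-0.87 ± 0.28) and PTPRC (-1.85 ± 0.60) passed adjusted over the list alone. HBB read 9.20 to 13.6 in old males and 10.5 to 15.4 in old females. All 7 lymphocyte markers had a lower mean (median -0.52), among them IGKC (-2.11 ± 1.01). The mean of this list was 2.10 in old female 6, a divergent sample. It was -0.52 to 0.28 in the other old females and -0.58 to 0.02 in old males. Smooth muscle genes had a median of 0.38 with 20 of 21 higher in males, led by ACTG2 (1.04 ± 0.37) and CSRP1 (0.50 ± 0.21). Ribosomal proteins lay lower (-0.11, 36 of 42), as did the cytokine (-0.23), proliferation (-0.23), matrix protease (-0.22), interferon (-0.16) and DNA repair (-0.13) lists, and MMP9 (-1.42 ± 0.40) passed adjusted over the matrix protease list alone. Higher medians were measured for adipocyte markers (0.63), cholesterol synthesis (0.30), the proteasome (0.15, but -0.06 without the 6 divergent samples) and oxidative phosphorylation (0.14). Over the alternatives, adipocyte markers came as close to 0 as 0.11, lymphocyte markers as -0.09, cytokines as -0.07, cholesterol synthesis as 0.04, and the interferon and DNA repair lists as -0.03. Apart from the X-linked list, the 14 calls had adjusted p-values of 0.466 to 0.716 with an estimated correlation. The oxidative phosphorylation median turned to -0.12 without old male 4, and 9 lists were called without old female 3.

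**Figure D5:**
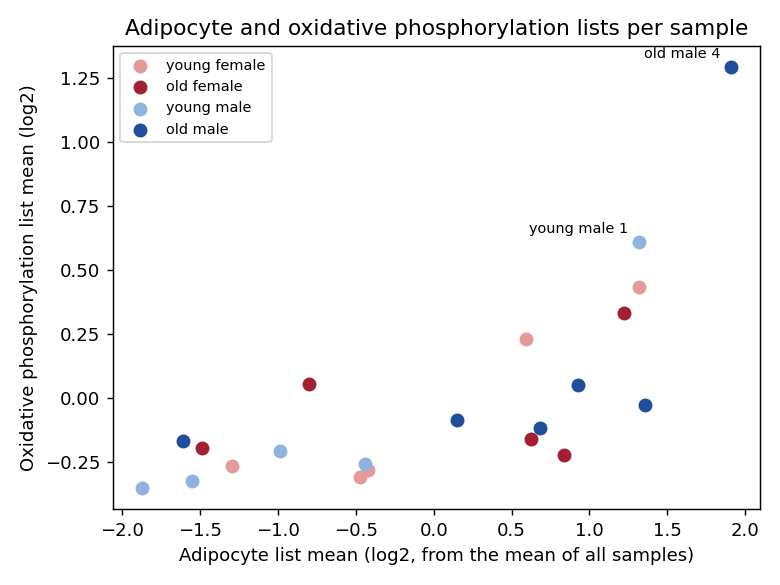
Mean of the oxidative phosphorylation list against the mean of the adipocyte list in each of the 21 samples, as log2 deviations from the mean over all samples. The lists correlate at r = 0.71.

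Across the 21 samples, the mean of the adipocyte list correlated with that of oxidative phosphorylation (r = 0.71, permutation p = 4e-05, adjusted 6e-05; rho 0.75, p = 0.00015, adjusted 0.000225) and of fatty acid oxidation (r = 0.78, p = 1e-05, the smallest that 100000 resamples can give, adjusted 3e-05; rho 0.84, p = 1e-05, adjusted 3e-05). The relation with the collagens did not pass (r = -0.38, p = 0.0852; rho -0.41, p = 0.0693). All 3 relations computed are given, and all tests are 2-sided. Without young male 6 and old male 3, the samples farthest from the median of the adipocyte list, r was 0.71, 0.75 and -0.45, and without the 6 divergent samples it was 0.81, 0.85 and -0.0350 over 15 samples.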

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

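The splits of the samples were planned before their results were seen; the tests of fat, of a single sample, of array quality, of cell content, of mixed RNA and of noise were chosen only after the result was seen, and their bounds were revised once after the values were known. Under the first bounds, array quality had been counted as excluded for all 3 patterns and a lower content of smooth muscle cells and fibroblasts as excluded for both matrix lists, while fat stayed undecided for these lists. The noise test was added last.

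The first pattern is that the adipocyte and oxidative phosphorylation lists lay higher in old than in young males, in camera calls that were lost with an estimated correlation (adjusted p = 0.492 and 0.551). With the adipocyte list mean as a covariate, the oxidative phosphorylation median went from 0.28 ± 0.25 to -0.0586 ± 0.204 (camera adjusted p from 1.22e-05 to 0.512), and without old male 4 it was 0.0181 ± 0.186 (adjusted p = 0.494). Here and below, the error beside a list median is the SE of the list mean over samples, not of the median. The same covariate took fatty acid oxidation from 0.36 ± 0.36 to -0.15 ± 0.26 (adjusted p = 0.432), cholesterol synthesis from 0.35 ± 0.18 to 0.25 ± 0.14 (0.113) and glycolysis from 0.14 ± 0.11 to 0.07 ± 0.09 (0.406), so these calls were lost as well, while the adipocyte list kept its call without old male 4 (1.10 ± 0.73, adjusted p = 0.000122) and with the hybridisation-control signal as a covariate (1.27 ± 0.62, adjusted p = 8.28e-06). Fat attached to the sampled aorta, and the weight of 1 sample, are candidate explanations for oxidative phosphorylation. With the hybridisation-control signal as a covariate, its median hardly moved (0.26 ± 0.25) and its call stayed (camera adjusted p = 9.96e-05). The error of the list mean was nearly as large as this median, so array quality cannot be told apart. A difference in the vessel or its fat with age stays open and untested.

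The second pattern is that the collagen and elastic fibre lists lay lower with age over both sexes. For the collagens (-0.42 ± 0.17), the median stayed near its value with each covariate. It was -0.415 ± 0.167 with the hybridisation-control signal, -0.39 ± 0.17 with the adipocyte list, and -0.40 ± 0.15 with the smooth muscle and fibroblast lists. For array quality and for cell content, these values argue against what the covariate measures as the whole cause. Fat stays undecided for the collagens, since its outcome hung on bounds that were revised after the values were known. The covariates only stand in for array quality, fat and cell content, so a part that they do not track stays open. For the elastic fibre list (-0.37 ± 0.26) the same covariates gave -0.21 ± 0.18, -0.18 ± 0.26 and -0.19 ± 0.22, so array quality, fat and cell content cannot be told apart there. The medians moved toward 0 by less than the errors of the list means, and the calls stayed (camera adjusted p = 0.00377, 0.0343 and 0.0203). Both calls were lost with an estimated correlation, at an adjusted p of 0.767. An effect of age stays open and untested.

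The third pattern is the XIST signal of young male 1, which lay far from the other young males on both probe sets (Dixon ratios 0.7501 on the brighter and 0.7469 on the other). RNA of a female sample, at the share of 30.1% that XIST would need, should leave Y-linked signals at 0.699 of the other young males, and the measured median over 10 probe sets was 0.950, with 0.767 to 1.18 among the other young males. RPS4Y1 (0.565), EIF1AY (0.591) and DDX3Y (0.557 and 0.0829) lay below 0.699, and KDM5D (1.54), UTY (0.740, 1.16 and 1.81), TMSB4Y (1.88) and TXLNGY (4.16) above it. Every male sample lay above every female one on these probe sets of RPS4Y1, EIF1AY and KDM5D and on the DDX3Y probe set at 0.557. On the DDX3Y probe set at 0.0829 the sexes overlapped. The 0.699 leaves out the intensity that these probe sets read in young females. For TXLNGY this was 42.2 against 86.5 in the other young males, and for RPS4Y1 188.5 against 7012. The divergent old males 2 and 4 lay at least 1.13 below young male 1 for XIST (log2). Of the probe sets at XIST's level in the other young males, 1.55% rose at least as much in young male 1 as the dimmer XIST probe set (2.12). The brighter one rose by 3.49. The share from XIST was 0.294 on the dimmer and 0.309 on the brighter probe set. The 1.55% was counted over single probe sets, so it does not cover both XIST probe sets rising together. Mixed RNA, array quality and noise cannot be told apart with these values, which go both ways, and no biological explanation was tested.

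Other groups of samples had 1 member far from the rest, in 22 of the 132 groups examined, XIST included, with 6.6 expected by chance. Young male 1 stood apart for the second ACAN probe set (Dixon ratio 0.7345; 8.97 against 7.11 to 7.61) and in the means of the oxidative phosphorylation (0.8469), heat shock (0.8134), proteasome (0.8112), fatty acid oxidation (0.764), ion channel (0.7581) and insulin and IGF (0.7258) lists. Young female 3 stood apart in the proliferation (0.7963), cytokine (0.8004), smooth muscle (0.7959) and elastic fibre (0.7323) lists. Old male 4 stood apart in oxidative phosphorylation (0.8507; 1.29 against -0.17 to 0.05), cholesterol synthesis (0.6878), MHC class II (0.6867) and glucocorticoid targets (0.666), and old male 2 in the proteasome (0.6622) and DNA repair (0.639) lists. These 4 samples are divergent ones. Old female 3 stood apart in the proliferation list (0.8064), old female 5 in the X-linked list (0.8084) and young male 2 in skeletal and cardiac muscle markers (0.7126).

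The age effect differed between the sexes for 12 lists in camera, and for 0 with an estimated correlation. The adjusted p was 0.004129 for adipocyte markers, cholesterol synthesis, the proteasome and ribosomal proteins, 0.004329 for oxidative phosphorylation, 0.007368 for fatty acid oxidation, 0.0137 for glucocorticoid targets, 0.01509 for glycolysis, 0.02354 for proliferation, 0.03005 for insulin and IGF genes, and 0.03434 for smooth muscle and heat shock genes.

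Each count was compared with 100 splits of the samples, the real one included. Few splits gave as many calls for the 2 probe sets of the male age comparison (1 split, highest other 1), the 3 of the sex comparison in young animals (1 split, highest other 1) and the 3 in old animals (4 splits, highest other 1747). The 2 in males both read ACAN, so they stand for 1 gene, whose call depended on the processing. A count over 100 splits makes chance less likely there and does not exclude it. The splits cannot decide on the 0 probe sets in females, over both sexes and in the interaction, which all 100 match by construction, the highest others being 9, 255 and 4.

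For the number of lists called, chance cannot be excluded in any comparison. The other splits called a median of 7 lists in males, in females and over both sexes. In the interaction and in both sex comparisons their median was 8. Camera with the preset correlation thus often called lists without the real groups, so its adjusted p-values for single lists overstate the evidence. As many were called in 10 splits for males (real 11, highest other 13), 53 for females (7 and 17), 40 over both sexes (9 and 19), 18 for the interaction (12 and 16), 18 for the sexes in young animals (12 and 19) and 6 in old animals (14 and 17). The correlation of the age effects, 0.23, was matched in 25 splits, with 0.42 as the highest other. The splits with 255 and 1747 probe sets point to a structure of the samples, since divergent samples made up 0 of 11 samples against 6 of 10 in the first, and 0 of 6 against 4 of 5 in the second.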

How the results depend on the processing

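The count of 24 arrays, the fits without 6 divergent samples, the covariates, the X-linked list without XIST and, for the gene lists, every setting but the estimated correlation, fry, no filter, the deposited scale and the replicate block were tests chosen after seeing the data. The cause of the changes below was not tested. The 2 probe sets of the male age comparison, both ACAN, became 0 with median-centred arrays, no filter, a pseudocount of 64, no intensity trend or only the 2 groups compared, 1 with 1 probe set per gene, the hybridisation-control covariate or the actin covariate, and 20 with array weights. The first ACAN probe set kept a log2 change of 2.74 to 3.52 and passed in 12 of 26 alternatives, with adjusted p-values of 0.000344 to 0.196. Leaving out 1 sample gave 0 to 2: 0 without old male 1, 2, 5 or 6 or young male 2, 3, 5 or 6, and 1 without young male 1. Without the 6 divergent samples, AKR1B10 passed beside ACAN in males, for 3 calls, and alone over both sexes, where 0 became 1 (log2 change 1.62, adjusted p = 0.0425). The 3 probe sets of the sex comparisons became 5 in young and 6 in old animals with no filter, which admits dim Y-linked genes, and 2 in each with the stricter filter or 1 probe set per gene. In young animals there were 4 with array weights and 2 with only the 2 groups compared, where the brighter XIST probe set lost its call (adjusted p = 0.0606). Leaving out 1 sample kept 0 calls in females, over both sexes and in the interaction, and 3 in each sex comparison.

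With an estimated correlation, and likewise in fry, 0 lists were called in each of the 3 age comparisons and in the interaction, and 1, the X-linked list, in each sex comparison. That list lost both calls without XIST (adjusted p = 0.203 in young and 0.142 in old animals with an estimated correlation, 0.575 and 0.175 in fry) and kept its preset-correlation calls. In females, 7 lists became 4 with median-centred arrays, 2 with array weights, 1 with 24 arrays, 2 without the 6 divergent samples, and 3 with the hybridisation-control covariate or with the actin covariate. Over both sexes, 9 became 14 with array weights, the interaction had 3 without the 6 divergent samples, and the sex comparison in old animals 8 with the stricter filter on the mean. A trended variance in camera gave 11, 7, 9, 13, 13 and 15 lists. Leaving out 1 sample gave 8 to 14 lists in males, 0 to 9 in females (0 without old female 6, 4 without young female 1), 6 to 14 over both sexes (14 without young female 3), 5 to 14 in the interaction (5 without young female 2, 7 without young female 6), 5 to 16 for the sexes in young animals (6 without young female 3, 6 without young male 5, 5 without young male 6) and 9 to 17 in old animals (9 without old female 3).

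Medians that crossed 0 were those of oxidative phosphorylation between the sexes in old animals (-0.0206 with array weights, -0.134 at an adjusted p of 0.00746 without the 6 divergent samples, -0.12 without old male 4; leaving out 1 sample gave at most 0.231, without old female 5), smooth muscle genes in the interaction (-0.000505 with 24 arrays, -0.0277 without old female 6) and in young animals (leaving out 1 sample gave -0.0207 without young female 3 to 0.214 without young female 6), and the proteasome in females (0.00215 without the 6 divergent samples) and between the sexes in old animals (-0.0579 without the 6 divergent samples, and also below 0 without old female 2). So did those of endothelial markers in males (-0.0519) and matrix proteases in young animals (0.0295), both without the 6 divergent samples, ribosomal proteins in females (-0.0213 with median-centred arrays) and the elastic fibre list in females (0.0130 with the actin covariate). The collagen list over both sexes lay at -0.58 to -0.35 in 37 alternatives and kept its call in 35, losing it with an estimated correlation and in fry. The elastic fibre list over both sexes lay at -0.49 to -0.13 and kept its call in 34 of 37.

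Whether replicate numbers pair animals was not settled. Of 36 same-numbered pairs of arrays, 16 correlated above 0.1, with no such count made for other pairs. The best partner in another group had the same number for 5 of 24 arrays. With the replicate number as a replicate block, 2, 0, 1, 0, 3 and 3 probe sets were called, the 1 over both sexes being ACAN (2.02, adjusted p = 0.0285), and 9, 8, 9, 14, 13 and 17 lists, while the oxidative phosphorylation median between the sexes in old animals was -0.12. After averaging, old male 4 alone carries its number, so the block takes this sample out of the comparisons.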

Other observations

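The genes below were chosen after their values were seen, and no tests of an explanation were run on them. None passed over all probe sets, except ACAN in males. In the list of vascular calcification and bone genes, which camera did not call in any age comparison, 3 of 10 members passed over both sexes when adjusted over the list alone. ACAN (1.85 ± 0.37) and SPP1 (1.56 ± 0.56), which encodes the matrix protein osteopontin, had higher means in old animals, and ENPP1 (-0.69 ± 0.17), whose enzyme makes pyrophosphate, a lower one. The other members did not pass, so these 3 do not describe the list as a whole. SPP1 read 10.4 ± 2.47 in old females, 8.78 ± 1.20 in old males, 8.15 ± 0.54 in young females and 7.90 ± 0.53 in young males (SD, n = 5, 6, 5 and 5).

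Of 11 circadian clock genes, 2 passed over both sexes when adjusted over the list alone, both with lower means in old animals: PER2 (-0.71 ± 0.20) and CRY1 (-0.82 ± 0.28), which encode repressors within the clock. PER2 read 9.61 ± 0.42 in old and 10.24 ± 0.27 in young females, and 9.96 ± 0.44 in old and 10.75 ± 0.68 in young males. The median of the list was -0.22, and camera did not call it (adjusted p = 0.317). CLOCK was at 0.55 ± 0.31. Times of day of sampling are not given in the sources used here.

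Some transcripts of tissue next to the vessel wall varied widely between samples of all groups. HBB read 8.98 in young female 3 and 15.4 in old female 6 (mean log2 intensity). UCP1, a marker of brown fat, read 13.3 in young female 2, 12.2 in old male 4, 12 in old female 5, 11.5 in old female 6, 11.2 in old male 5 and 10.8 in young female 6, and 5.26 to 8.56 in the other samples. FABP4, a fatty acid carrier of adipocytes, read 9.35 in young male 6 and 14.7 in young male 1.

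The series states that about 600 genes differed between old and young animals. Its test and threshold are not given in the sources used here, and limma found 485 probe sets at an unadjusted p below 0.05 over both sexes, against 555 expected by chance, and 0 past the adjusted threshold.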
